A study of Homo sapiens with 7 samples.

How the data were processed

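The deposited gene by barcode matrices of counts were taken from the repository as the authors supplied them, 1 per library. Per the file headers the untreated and MI libraries were counted with Cell Ranger 3.1.0 against 33538 genes and the CI libraries with Cell Ranger 6.0.1 against 36601 genes. Per the submitters' processing notes reads were processed with Cell Ranger, whose version those notes did not give, and with Seurat 3.1.1, for which no step was given. The genome build and gene annotation were not given in the sources used here. Per the labels' protocols the cells were primary adult dermal fibroblasts grown to confluence on the device, the hairpins were delivered at 50 nM by a pulsed electric field, cells were harvested after a day and put in endothelial medium, and libraries were made with the 10x Genomics Chromium 3' chemistry. The hairpin was thus confounded with the software version and gene list, and the labels did not say whether all cells came from the same culture.

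Only the 32732 genes listed in every library were compared, matched by Ensembl ID, of which 32551 were present in GENCODE v44, the source of names, coordinates, exons and 3' UTRs. Barcodes were kept as cells with at least 500 genes, 1000 UMIs and at most 20% mitochondrial UMIs. Counts were summed over the kept cells of a library and scaled to the library's total (CPM). A log2 ratio was taken between the CPM values of the libraries, with intervals from the exact conditional binomial distribution of the summed counts, and with the difference between courses taking its interval from repeated gamma draws around the counts of its 4 libraries. Where a library held 0 UMIs, the fold was given as at least the value for the 3 UMIs that a count of 0 allows. Genes entered a count of higher or lower genes at 20 CPM in a compared library and at a ratio of 2-fold. The alternatives were TMM factors across the 7 libraries, a total without mitochondrial and ribosomal protein genes, a 1.5-fold threshold, a floor of 100 CPM, no floor with 1 CPM added, all barcodes, a stricter cell filter, equal weight per cell, non-cycling cells, other thinning depths and UMI limits, Leiden resolution 1.0, the longer seed match and the shortest 3' UTR. High-complexity cells, cells with at least 0.2% of UMIs from MALAT1 and NEAT1, and the leaving out of overlapping genes were added after seeing the data. No tests were made, because every group held 1 library.

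Gene lists were written before the data were examined and were used as they stood: endothelial identity, ETS and vascular transcription factors, angiogenic factors, reported miR-200b targets, fibroblast matrix, basement membrane, contractile, TGF-beta response, matrix proteases, NF-kB and cytokines, interferon, immediate early, heat shock, unfolded protein and integrated stress response, hypoxia, cholesterol synthesis, p53, S phase, G2 and M phase, glucocorticoid response, Notch, microRNA machinery, chromatin modifiers, mitochondrially encoded transcripts, common reference genes, and markers of keratinocytes, pericytes, Schwann cells and adipocytes. The melanocyte and immune lists had 1 measured gene each and were given no median. A list's members counted at 1 CPM and its median was placed among 10000 random lists drawn from 20 bins of expression, as a description of these libraries. Genes were named by a rule written beforehand: for MI against CI on each day, MI day 7 against untreated cells and the difference between courses the 10 highest and 10 lowest log2 ratios at 50 CPM, for the other comparisons 5 and 5, up to 4 members of each list at 10 CPM, FLI1, ETS1, KDR, ZEB1, ZEB2, GATA2, PECAM1, CDH5, VWF, TEK, COL1A1, ACTA2 and MKI67 always, and the top genes of clusters. Y-linked genes, XIST, mitochondrially encoded genes, ribosomal protein genes and clone names were left out of the named genes, and 106 genes in all, among them highly polymorphic ones, were left out of the tables to protect the donors. MALAT1, NEAT1, FTL and the examples of genes ordered over the days were chosen after their values were seen.

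For shares of cells, each cell was reduced at random to 5000 UMIs, the largest of the depths tried that kept at least 80% of the cells of every library, and Clopper-Pearson intervals at 95% were computed. A cell was called low in complexity under 1400 genes at that depth, a limit set after the distribution was seen, and the share within 100 genes of the limit was 5.82% of untreated cells, 5.18%, 3.92%, 12.2% and 7.60% of MI cells and 1.79% and 8.26% of CI cells. Clustering used scanpy 1.11.5 with 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 0.5 with igraph 0.11.9 and seed 1. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9. Seed matches to the mature sequence UAAUACUGCCUGGUAAUGAUGA were sought in the 3' UTRs of GENCODE v44 and compared with all 420 permutations of the bases of the match.

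In a self-test, Poisson counts at each library's depth were drawn from 1 pooled profile, with known differences put into MI day 1. Among 4868 genes of MI day 1 against CI day 1, 100 of 100 with a 3-fold difference were called. Of those with a 1.4-fold difference 0 of 100 were called, and of those without one 0 of 4668. No spread or scaling shift between libraries was simulated, so this checked the calculation and not the rate of false calls. A check of sample origin by genes whose levels are not shown found 2 of 7 libraries unlike the majority. Doublet calling found almost no doublets in any library, so it was taken as not working, and the planned analysis without doublets was left out.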

Results

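Single-cell RNA was counted in primary human adult dermal fibroblasts after a hairpin inhibitor of miR-200b-3p was delivered by nanochannel electroporation, to follow their transcripts over the days after delivery. The cells were put in endothelial medium after a day. There were 7 libraries, 1 per group. They came from untreated cells, cells given the inhibitor (MI) and sampled on days 1, 3, 5 and 7, and cells given a negative control hairpin (CI) and sampled on days 1 and 7. The deposited counts held 8334 barcodes for untreated cells, 6250, 5643, 8754 and 11395 for MI on days 1, 3, 5 and 7, and 5391 and 4471 for CI on days 1 and 7. Of these, 7905, 5204, 5423, 7825, 10450, 3652 and 2702 were kept as cells. The libraries held 171911023, 162488882, 166293735, 159451466, 172399185, 138098978 and 120374664 UMIs in the same order. The median cell held 19702, 29970.5, 28216, 14711, 11967.5, 36888.5 and 21049.5. With 1 library per group there was no replicate check, so the values describe these libraries, and the intervals carry counting error only. A fold or share in parentheses is followed by its 95% interval.

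The genes on which most of the text rests lie on GRCh38 (GENCODE v44) as follows. The endothelial receptor KDR (ENSG00000128052) lies on chromosome 4 from 55078481 to 55125595, and the endothelial transcription factors ETS1 (ENSG00000134954) and FLI1 (ENSG00000151702) lie on chromosome 11 from 128458761 to 128587558 and from 128686535 to 128813267. The classical miR-200b targets ZEB1 (ENSG00000148516) and ZEB2 (ENSG00000169554) lie on chromosome 10 from 31318495 to 31529814 and on chromosome 2 from 144364364 to 144521057. The cholesterol synthesis gene HMGCS1 (ENSG00000112972) lies on chromosome 5 from 43287470 to 43313512, the collagen gene COL1A1 (ENSG00000108821) on chromosome 17 from 50184101 to 50201632, and the collagenase gene MMP1 (ENSG00000196611) on chromosome 11 from 102789401 to 102798160. The mature microRNA itself is not read by this assay, so the extent of its inhibition was not measured.

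Cells with a UMI of the proliferation genes MKI67 or TOP2A were most common on day 3 of the inhibitor and least common on day 7 of either hairpin. Among cells reduced to 5000 UMIs each, a UMI of MKI67 or TOP2A was found in 11.8% (11.1 to 12.6) of untreated cells, and in 10.1% (9.21 to 10.9), 28.5% (27.3 to 29.7), 7.91% (7.28 to 8.57) and 3.18% (2.83 to 3.56) of MI cells on days 1, 3, 5 and 7. It was found in 14.8% (13.6 to 16.0) and 3.48% (2.77 to 4.31) of CI cells on days 1 and 7. Without the reduction the shares were 21.7%, 20.7%, 47.6%, 14.4% and 6.71% in the untreated and MI libraries and 26.9% and 8.92% in the CI libraries. Among high-complexity cells, those with at least 1400 genes at the reduced depth, they were 12.2%, 10.7%, 32.4%, 13.4% and 5.99%, and 15.1% and 8.69%. The cells that reached 5000 UMIs were 97.6% of untreated cells, 92.0%, 96.4%, 87.1% and 88.2% of MI cells and 93.2% and 85.1% of CI cells.

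A second class of cells expressed few genes for their depth and held less of MALAT1, a transcript that stays in an intact nucleus, than the other cells. Cells with fewer than 1400 genes among 5000 UMIs were 3.79% (3.37 to 4.24) of untreated cells and 7.67% (6.93 to 8.46), 14.0% (13.0 to 14.9), 46.1% (44.9 to 47.3) and 52.8% (51.7 to 53.8) of MI cells on days 1, 3, 5 and 7. In the CI libraries they were 2.32% (1.84 to 2.89) and 61.9% (59.9 to 63.9) on days 1 and 7. On day 7 of MI these low-complexity cells held MALAT1 at 864 CPM against 24400 CPM in the other cells, and on day 1 of MI at 9300 against 25600 CPM. The day 1 sum was carried by a minority of the class. Its median share of UMIs on MALAT1 and NEAT1 was 0.0255% (upper quartile 0.0404%), against 2.57% in the other day 1 MI cells. On day 7 of MI they held COL1A1 at 44.1 against 669 CPM, while the ferritin gene FTL stood at 12700 against 6320 CPM. MALAT1 and FTL were chosen after their values were seen. Among cells with at least 5000 UMIs, the low-complexity cells supplied 29.9% of the day 7 MI UMIs and 30.3% of the day 7 CI UMIs. The counts of higher and lower genes that involve the late libraries, and some of the medians, are therefore also given for the high-complexity cells alone.

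**Figure D1:**
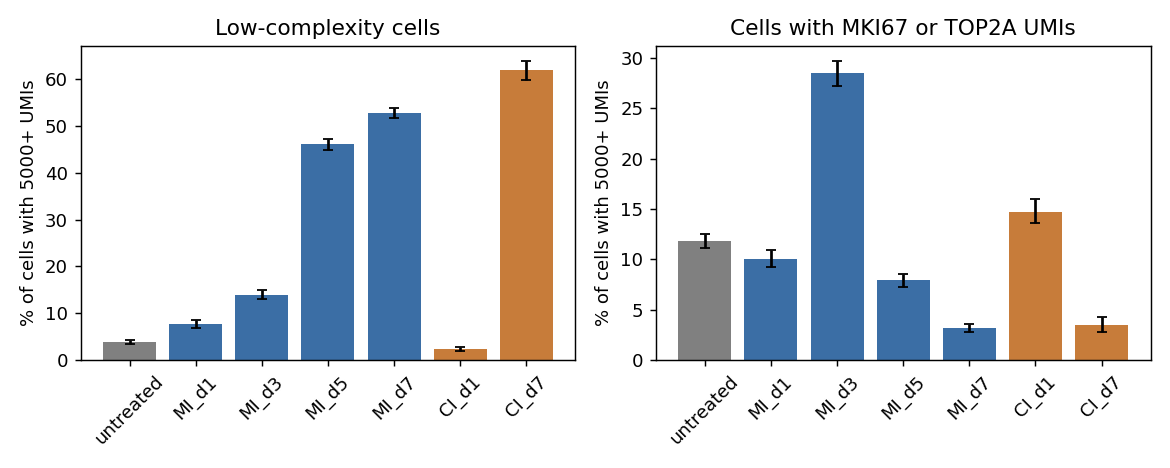
Shares of low-complexity cells and of cells with an MKI67 or TOP2A UMI in each library, among cells with at least 5000 UMIs. Error bars are 95% exact binomial intervals for counting error.

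On day 1, cells given the inhibitor held more transcripts of the collagenase MMP1 and of the growth factor binding protein IGFBP2 than cells given the control hairpin, and fewer of interferon, p53 and basement membrane genes. MMP1 was 15.7-fold higher (14.6 to 16.9) and IGFBP2 8.67-fold higher (8.39 to 8.95). Among the genes with the highest ratios were ROMO1, ATP5ME, NDUFA3 and NDUFB1, nuclear genes of small mitochondrial proteins, at 6.81-fold to 8.36-fold. No list of such nuclear genes was examined, so they say nothing of the others. Of 13 transcripts of the mitochondrial genome 10 were lower and 1 higher (median log2 -1.02, and -0.58 under TMM factors). Of 24 interferon genes, which cells turn on in an antiviral state, 17 were at least 1.5-fold lower and 1 higher (median log2 -1.10), among them MX1 (log2 -2.38) and IFI44L (log2 -2.21). Of 16 p53 response genes 11 were lower and 0 higher (median log2 -0.91, MDM2 -1.44), and of 12 basement membrane genes 7 were lower and 0 higher (median log2 -0.87, NID1 -1.19, COL4A1 -1.10). Under TMM factors the medians of these lists were nearer 0, at -0.65, -0.47 and -0.42, but the median of all genes then stood at 0.32. The kept CI cells of day 1 had a median mitochondrial share of 7.41%, against 4.16% in the MI cells. Of CI barcodes 14.9% were over the mitochondrial limit, and of MI barcodes 10.5%. Of 12 heat shock genes 4 were higher and 0 lower (median log2 0.44, and 0.88 under TMM factors, HSPB1 1.41), and of 19 hypoxia and glycolysis genes 7 were higher and 2 lower (median log2 0.31, and 0.75 under TMM factors, ENO1 1.16). Of 29 fibroblast matrix and identity genes 13 were lower and 3 higher (median log2 -0.48, and -0.03 under TMM factors, FBLN2 -2.22, POSTN -1.84). Across 5862 genes measured at 20 CPM or more, 352 were at least 2-fold higher and 651 lower. Their median log2 was -0.22. Random lists matched for expression and 3' UTR length to the genes with a seed match, described below, had a median of -0.483. Those random lists were not matched to the gene lists here, so their median was only a rough mark. List medians near these values were not taken to set a list apart. TMM factors shifted the median of all genes by 0.54, to 0.32, and gave 849 higher and 181 lower. The split between higher and lower genes thus depended on the scaling, and neither scaling put the median of all genes at 0.

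The endothelial program was not higher with the inhibitor on day 1. Of 17 endothelial identity genes measured, 1 was at least 1.5-fold higher and 9 lower (median log2 -0.66, and -0.22 under TMM factors). The 1 that was higher was KDR, the receptor through which endothelial cells respond to vascular growth factor, at 5.99 CPM (962 UMIs) with the inhibitor, 3.12 CPM (533 UMIs) in untreated cells and 5 UMIs with the control hairpin (161-fold, 68.8 to 498). PECAM1 differed little (log2 -0.06), VWF was lower (log2 -1.87), and CDH5 and TEK were too few to compare. Because KDR was nearly absent from both CI libraries, which were counted against another gene list, its ratio to CI was taken as uncertain. Among 15 ETS and vascular transcription factors 7 were lower and 0 higher (median log2 -0.42, 0.03 and so of the opposite sign under TMM factors), with FLI1 at log2 -1.45, ETS1 at 0.14 and GATA2 at 0.57. Angiogenic growth factors and receptors had 7 of 22 lower and 1 higher (median log2 -0.44, which became 0.00 under TMM factors).

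On day 7, cells given the inhibitor held fewer TGF-beta response and basement membrane transcripts than cells given the control hairpin, and more of the secreted antiangiogenic protein SERPINF1 and the detoxifying enzyme GSTM3. GSTM3 was 5.58-fold higher (5.29 to 5.89) and SERPINF1 3.50-fold higher (3.41 to 3.59), while CD36, a fatty acid receptor, was 144-fold lower (113 to 186). CD36 was a top gene of a cluster that held 22.5% of the CI cells of day 7, with a median of 115930 UMIs per cell. Of 14 TGF-beta response genes 10 were at least 1.5-fold lower and 0 higher (median log2 -1.22), among them BHLHE40 (log2 -3.21), TGFBI (log2 -1.79) and INHBA (log2 -1.52). Of 12 basement membrane genes 8 were lower and 0 higher (median log2 -1.09, COL4A1 -2.85, COL4A2 -2.01), and of 6 Notch genes all 6 were lower (median log2 -1.42, NOTCH3 -1.63). Angiogenic growth factors and receptors had 13 of 22 lower and 1 higher (median log2 -0.75, EFNB2 -2.41, VEGFA -1.20). ETS and vascular factors had 8 of 15 lower and 1 higher (median log2 -0.71, EPAS1 -2.25, KLF2 -1.43), and endothelial identity genes 8 of 17 lower and 2 higher (median log2 -0.55). Under TMM factors the TGF-beta, basement membrane, Notch, angiogenic, ETS and vascular, and endothelial medians were -0.82, -0.69, -1.02, -0.35, -0.31 and -0.15. Adipocyte genes had 3 of 4 lower (median log2 -3.51, and -3.11 under TMM factors) and pericyte genes 5 of 9 lower (median log2 -0.92, and -0.30 under TMM factors). Mitochondrial transcripts had 10 of 13 lower and 0 higher (median log2 -1.22, and -0.82 under TMM factors), and 32.5% of CI and 3.47% of MI barcodes were over the mitochondrial limit. KDR again stood at 2 UMIs with the control hairpin and 172 with the inhibitor (log2 5.83, fold interval 15.5 to 474). Fibroblast matrix genes had 10 of 29 lower and 3 higher (median log2 -0.34, but 0.06 and so of the opposite sign under TMM factors, POSTN -4.47). Across 5018 genes 127 were at least 2-fold higher and 451 lower, in high-complexity cells 137 and 610, and under TMM factors, with a shift of 0.45, 460 and 194. The median log2 of these genes was -0.23, and 0.22 under TMM factors. That of the random lists matched to genes with a seed match was -0.478.

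Much of the difference between the hairpins was the same on the first and the last day. Of 4874 genes measured on both days, 94 were at least 2-fold higher with the inhibitor on both, where independent lists of 304 and 119 would share 7.42. Another 238 were lower on both, where lists of 466 and 414 would share 39.6. In high-complexity cells 94 were higher and 310 lower on both, where independent lists would share 7.5 and 53.4. Across genes, which are not independent replicates, the log2 ratios of the 2 days correlated at 0.85. The CI counts came from a later Cell Ranger version with a longer gene list, so genes whose exons overlap a gene listed in only some libraries were taken as uncertain. They made up 75 of the 332 shared genes (22.6%) and 330 of all 4874 (6.77%), and included 10 of the 20 named extremes of day 1. These were TOMM6, PLSCR3, EEF1G, PIK3R2, TUBB3, TRAPPC5, C17orf49 and ATP6V0C among the 10 lowest of day 1, and PTP4A1 and FKBP2 among the 10 highest. EEF1G was 84.2-fold lower (81.3 to 87.3) on day 1, PTP4A1 1960-fold higher (767 to 7210), and TOMM6, with 0 UMIs outside the CI libraries, at least 16000-fold lower. None of these was taken as a difference between treatments. The readthrough gene PALM2-AKAP2 (368-fold lower, 301 to 454) and MTRNR2L8 (37.5-fold higher, 34.8 to 40.5), a nuclear copy of a mitochondrial RNA, were also uncertain because reads can pass to their paralogs or overlapping parts.

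**Figure D2:**
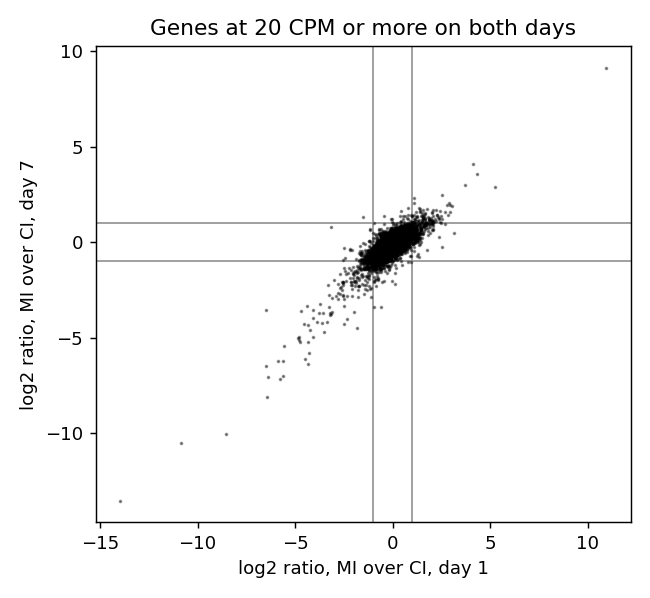
Log2 ratio of MI over CI on day 1 and on day 7 for genes at 20 CPM or more on both days. Lines mark 2-fold, and the points far from the centre include genes whose models differ between the gene lists.

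On day 1 most cholesterol synthesis genes were lower in cells given the inhibitor than in untreated cells, and the collagenase MMP1 was the highest named ratio. MMP1 was 6.95-fold higher (6.66 to 7.26), the calcium regulating hormone STC1 4.56-fold (4.42 to 4.72) and the MAP kinase phosphatase DUSP6 3.77-fold (3.66 to 3.88), and the pentraxin PTX3 was 8.91-fold lower (8.72 to 9.10). THBS1 and CCN2, which respond to YAP, were 3.77-fold and 3.62-fold lower. Of 18 cholesterol synthesis genes 15 were at least 1.5-fold lower and 0 higher (median log2 -0.90, HMGCS1 -1.59, ACAT2 -1.35), and of 12 matrix proteases 6 were higher and 0 lower (median log2 0.58, PLAU 1.34, PLAUR 1.10). Of 23 NF-kB and cytokine genes 11 were lower and 6 higher (median log2 -0.54, SOD2 -1.63, NFKBIA -0.96), and TGF-beta response genes had 7 of 14 higher and 2 lower (median log2 0.46, ID1 1.84, LTBP2 0.97). In all 32 genes were at least 2-fold higher and 54 lower.

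On day 3 the inhibitor library was marked by cell division genes, with nearly every member higher than in untreated cells. No control hairpin library was taken on this day. The inhibitor could thus not be told apart from the delivery, the new medium and time. Of 52 G2 and M phase genes 48 were at least 1.5-fold higher and 0 lower (median log2 1.49, HJURP 2.13, NUF2 2.11), and of 44 S phase genes 40 were higher and 0 lower (median log2 1.39, CLSPN 1.95, RRM2 1.81). All 18 cholesterol synthesis genes were lower (median log2 -1.93), led by HMGCS1 (12.0-fold, 11.6 to 12.4), and the fatty acid binding protein FABP3 was 16.4-fold lower (16.0 to 16.8). The NADPH oxidase subunit CYBA was 6.94-fold higher (6.67 to 7.24) and the actin binding protein TAGLN 5.96-fold (5.81 to 6.11), and the BMP response genes ID3 and ID1 stood at log2 4.51 and 3.80. Fibroblast matrix genes had 16 of 29 lower and 1 higher (median log2 -0.60, COL3A1 -2.33, COL5A1 -1.87), and interferon genes 12 of 24 lower and 0 higher (median log2 -0.58). At 2-fold, 140 genes were higher and 107 lower. The numbers were 34 and 140 in non-cycling cells, and 155 and 167 when mitochondrial and ribosomal protein genes were left out of the total, which shifted the median by -0.11.

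On day 5 inflammatory genes were higher than in untreated cells and matrix genes lower. This day also had no control hairpin library, so the inhibitor could not be told apart from delivery, medium and time. Of 23 NF-kB and cytokine genes 13 were at least 1.5-fold higher and 2 lower (median log2 0.71, CXCL5 2.74, CXCL3 2.37, CCL2 1.97), and the immediate early genes, which respond within minutes to stimuli, had 6 of 16 higher and 4 lower (median log2 0.22, FOSB 2.72). All 18 cholesterol synthesis genes stayed lower (median log2 -1.92, in high-complexity cells -1.61), with HMGCS1 8.26-fold lower (8.03 to 8.49). Of 29 fibroblast matrix genes 17 were lower and 0 higher (median log2 -0.63, COL3A1 -2.17), and the division genes were back near the untreated level (median log2 0.12 for S phase and 0.10 for G2 and M phase). At 2-fold 39 genes were higher and 131 lower, in high-complexity cells 52 and 82, and under TMM factors, with a shift of 0.15, 65 and 95. When each cell had equal weight, 48 were higher and 442 lower.

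On day 7 the complement genes C1S, SERPING1 and CFD were among the 10 highest ratios to untreated cells, and most fibroblast matrix, cholesterol, division and endothelial genes were lower. CYBA was 6.36-fold higher (6.11 to 6.63), TXNIP, which restrains glucose uptake, 5.59-fold (5.46 to 5.73) and the alcohol dehydrogenase ADH1B 4.33-fold (4.14 to 4.54). The complement genes C1S, SERPING1 and CFD were 3.95-fold (3.82 to 4.09), 3.63-fold (3.49 to 3.78) and 3.29-fold (3.19 to 3.40) higher. COL1A1 was 4.85-fold lower (4.81 to 4.89) and COL3A1 4.87-fold lower (4.82 to 4.91), and fibroblast matrix genes had 17 of 29 at least 1.5-fold lower and 1 higher (median log2 -0.73, in high-complexity cells -0.39). All 18 cholesterol genes were lower (median log2 -1.83, in high-complexity cells -1.41). So were 32 of 44 S phase genes (median log2 -0.80, in high-complexity cells -0.51) and 40 of 52 G2 and M phase genes (median log2 -0.95, in high-complexity cells -0.53). Of 17 endothelial identity genes 10 were lower and 0 higher (median log2 -0.89, in high-complexity cells -0.69). Under TMM factors the matrix, cholesterol, S phase, G2 and M phase and endothelial medians were -0.44, -1.54, -0.51, -0.65 and -0.59. KDR stood at log2 -1.63, PECAM1 at -0.78, VWF at -2.09, ETS1 at -0.51, GATA2 at -0.16 and FLI1 at 0.59. In high-complexity cells GATA2 went the other way, at 0.712 CPM against 0.571 CPM in untreated cells. ETS1 stood there at 24.8 against 28.4 CPM and FLI1 at 1.53 against 0.745 CPM, and KDR, PECAM1 and VWF stayed lower. GATA2 and FLI1 rested on 95 and 124 UMIs in the untreated library, so their ratios were imprecise and the direction of GATA2 was taken as uncertain. NF-kB and cytokine genes had 10 of 23 higher and 5 lower (median log2 0.13, in high-complexity cells 0.59, CCL2 2.82), and immediate early genes 6 of 16 higher and 4 lower (median log2 0.42, FOSB 2.87). The contractile list was level, with 4 of 16 higher and 3 lower (median log2 -0.01, and 0.15 with the opposite sign under TMM factors). At 2-fold 42 genes were higher and 200 lower, in high-complexity cells 70 and 84, and under TMM factors, with a shift of 0.31, 94 and 87. Equal weight per cell gave 39 higher and 890 lower.

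**Figure D3:**
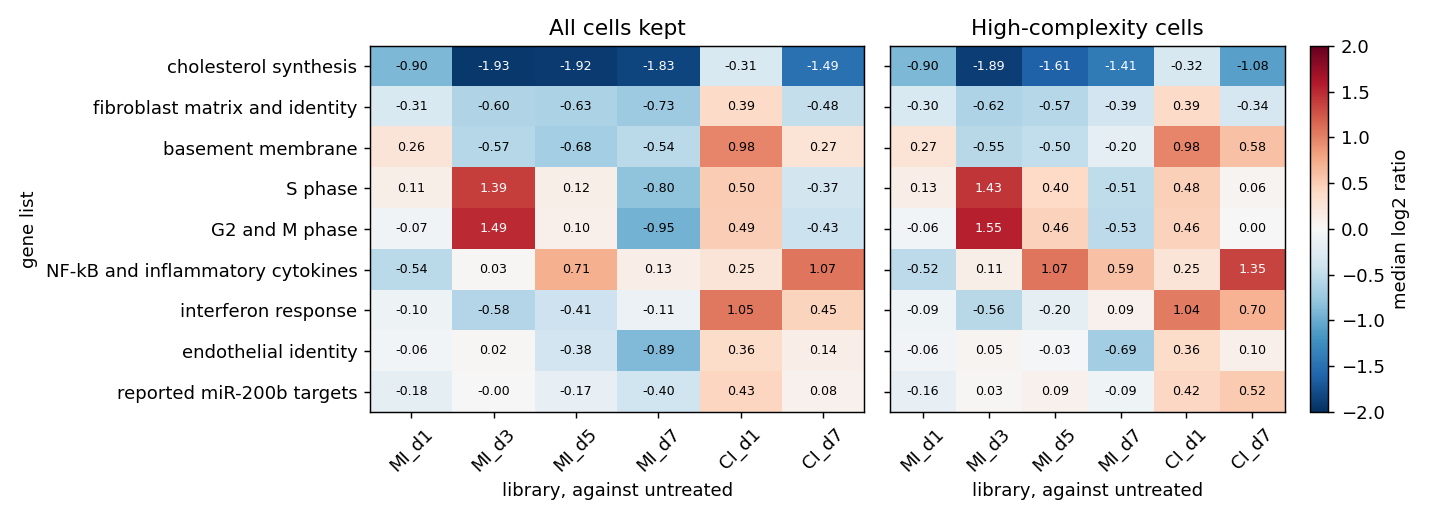
Median log2 ratio to untreated cells of 9 gene lists in all cells and in high-complexity cells. Under TMM factors the all-cell median changed sign for matrix, NF-kB, endothelial and miR-200b target genes in CI on day 1, miR-200b targets in CI on day 7, interferon genes in MI on day 7, and endothelial and NF-kB genes in MI on day 3.

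Cells given the control hairpin differed from untreated cells on day 1 by more genes than cells given the inhibitor did. The untreated library shared its software version and gene list with MI and not with CI. The control hairpin could thus not be told apart from the processing here. The joint lubricant proteoglycan PRG4 was 107-fold higher (98.2 to 117), and the Wnt inhibitor APCDD1 and IGFBP2 were 9.85-fold (9.15 to 10.6) and 8.28-fold (8.02 to 8.55) lower. Of 14 TGF-beta response genes 10 were at least 1.5-fold higher and 3 lower (median log2 1.41, LTBP2 1.66, INHBA 1.42), and of 24 interferon genes 15 were higher and 2 lower (median log2 1.05, MX1 2.96, ISG20 2.67). Of 12 basement membrane genes 8 were higher and 0 lower (median log2 0.98, COL4A1 1.99) and of 16 p53 genes 11 were higher and 0 lower (median log2 0.79, SESN1 1.51). Under TMM factors these medians were 0.97, 0.61, 0.54 and 0.36. Of 18 cholesterol synthesis genes 6 were lower and 3 higher (median log2 -0.31, and -0.74 under TMM factors). Contractile genes had 8 of 16 lower and 1 higher (median log2 -0.55, and -1.10 under TMM factors, TAGLN -1.80, MYL9 -1.57). Endothelial identity genes had 8 of 17 higher and 2 lower (median log2 0.36, but -0.08 and so of the opposite sign under TMM factors). At 2-fold 616 genes were higher and 291 lower, and under TMM factors, with a shift of -0.52, 182 and 755. The median log2 of all genes was 0.19, and -0.34 under TMM factors. The largest ratios, in TOMM6, EEF1G, PLSCR3, PTP4A1 and FKBP2, belonged to genes with overlapping models and were uncertain.

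On day 7 the control hairpin library held more inflammatory and TGF-beta response transcripts than untreated cells and fewer cholesterol synthesis transcripts. Here too the hairpin could not be told apart from the processing. Of 23 NF-kB and cytokine genes 12 were at least 1.5-fold higher and 4 lower (median log2 1.07, CCL2 4.71, LIF 2.78). Of 14 TGF-beta genes 10 were higher and 0 lower (median log2 0.94, ID3 4.41, TGFBI 2.19), and of 16 immediate early genes 8 were higher and 0 lower (median log2 0.70, FOSB 4.51, NR4A1 2.17). With equal weight per cell the immediate early median was -0.22, of the opposite sign. The 875 high-complexity cells of this library had a median of 94227 UMIs, and its 1424 low-complexity cells 19114.5. The deeper cells thus weighed more in the sums. CCL2 and FOSB were top genes of a cluster with a median of 115930 UMIs that held 22.5% of the library's kept cells. The cholesterol genes had 15 of 18 lower and 1 higher (median log2 -1.49, ACAT2 -3.17, HMGCS1 -2.84), FABP3 was 11.6-fold lower (11.3 to 11.8) and APCDD1 22.6-fold lower (20.1 to 25.5). The flow responsive factor KLF2 and the hypoxia factor EPAS1 stood at log2 2.62 and 2.55, while endothelial identity genes had 4 of 17 higher and 7 lower (median log2 0.14). At 2-fold 336 genes were higher and 376 lower, in high-complexity cells 688 and 246, and under TMM factors, with a shift of -0.12, 263 and 485. There were 270 higher and 1062 lower with equal weight per cell.

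Against the same untreated library, the hairpins shared 14 higher and 19 lower genes on day 1, where independent lists would share 1.36 and 3.18, and 27 higher and 90 lower genes on day 7, where independent lists would share 1.39 and 15.4. In high-complexity cells they shared 44 higher and 48 lower genes on day 7, where independent lists would share 4.48 and 4.09. Part or all of this excess may come from the shared control library, so it was not taken as a shared response. Across genes, which are not independent replicates, the log2 ratios of MI and CI to untreated cells correlated at 0.13 on day 1 and 0.47 on day 7, and ratios to a common library correlate without any shared response.

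Between day 1 and day 7 of the inhibitor, most NF-kB and cytokine genes were higher on the later day and most fibroblast matrix genes lower. ADH1B was 25.1-fold higher (22.6 to 28.0), the actin binding gene TAGLN stood at log2 3.91 (3.32 in high-complexity cells), PTX3 was 10.6-fold (10.3 to 10.8) higher and the mitochondrial superoxide dismutase SOD2 6.07-fold (5.92 to 6.22) higher. On the other side MMP1 was 26.2-fold (24.1 to 28.4, and 41.1-fold in high-complexity cells), the metalloprotease ADAM12 10.9-fold (10.2 to 11.7) and the transcription factor SOX4 9.27-fold (8.92 to 9.63) lower. NF-kB and cytokine genes had 14 of 23 at least 1.5-fold higher and 4 lower (median log2 0.86, CCL2 5.21), endothelial genes 10 of 17 lower and 2 higher (median log2 -0.90) and matrix genes 17 of 29 lower and 4 higher (median log2 -0.75, POSTN -3.54). These 3 medians were 1.15, -0.61 and -0.47 under TMM factors and 1.19, -0.63 and -0.37 in high-complexity cells. At 2-fold 78 genes were higher and 319 lower, in high-complexity cells 130 and 116, and under TMM factors, with a shift of 0.31, 172 and 124. Equal weight per cell gave 69 higher and 1013 lower.

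With the control hairpin, many of the same groups differed between the days in the same direction. TAGLN was 34.0-fold higher on day 7 (32.4 to 35.7), the chemokine CCL2 18.2-fold (17.0 to 19.5) and ID1 11.3-fold (10.5 to 12.3), and PRG4 was 12.4-fold (11.9 to 12.8) and HMGCS1 5.40-fold (5.23 to 5.57) lower. NF-kB and cytokine genes had 12 of 23 at least 1.5-fold higher and 4 lower (median log2 0.84, ICAM1 2.51), and matrix genes 18 of 29 lower and 1 higher (median log2 -0.86, COL3A1 -2.14). Cholesterol genes had 16 of 18 lower and 0 higher (median log2 -1.13) and endothelial genes 13 of 17 lower and 1 higher (median log2 -1.30). TGF-beta response genes had 7 of 14 higher and 5 lower (median log2 0.47, CCN2 1.96). These 5 medians were 1.17, -0.53, -0.80, -0.97 and 0.80 under TMM factors. At 2-fold 119 genes were higher and 253 lower, in high-complexity cells 190 and 88, and under TMM factors, with a shift of 0.39, 264 and 77. The numbers with equal weight per cell were 158 and 1885. Of 4617 genes measured in both hairpins, 35 were higher and 82 lower on day 7 in both, where independent lists would share 1.46 and 9.77, with a correlation of 0.61 across genes, which are not independent replicates. In high-complexity cells the balance turned, with 62 higher and 31 lower of 4908, where independent lists would share 3.64 and 1.25. The correlation was then 0.52.

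Relative to the control's course, most TGF-beta response and hypoxia genes were lower in the inhibitor's course, and the alcohol dehydrogenase ADH1B was the highest named gene. ADH1B was higher by 15.8-fold (14.1 to 17.7) in the inhibitor's course relative to the control's, the prostaglandin receptor PTGFR by 4.49-fold (4.17 to 4.84), CFD by 3.88-fold (3.68 to 4.10, with log2 1.96 against 2.75 in high-complexity cells) and C1S by 3.50-fold (3.32 to 3.68). IGFBP5 was lower by 6.94-fold (6.60 to 7.31), the protease inhibitor TFPI2 by 6.88-fold (6.68 to 7.09), POSTN by 6.20-fold (5.40 to 7.14) and ID1 by 4.71-fold (4.28 to 5.19). TGF-beta response genes had 8 of 14 at least 1.5-fold lower and 0 higher (median log2 -0.92, BHLHE40 -2.34). Hypoxia genes had 11 of 19 lower and 1 higher (median log2 -0.73, SLC2A1 -2.16) and immediate early genes 8 of 16 lower and 1 higher (median log2 -0.61, NR4A1 -5.51). Notch genes had 4 of 6 lower and 0 higher (median log2 -1.15), glucocorticoid response genes 8 of 15 lower and 4 higher (median log2 -0.75) and matrix proteases 6 of 12 lower and 0 higher (median log2 -0.66). Interferon genes had 11 of 24 higher and 1 lower (median log2 0.56, IFI27 1.68), p53 genes 7 of 16 higher and 0 lower (median log2 0.47, BBC3 1.69) and endothelial genes 5 of 17 each way (median log2 0.18). At 2-fold 96 genes were higher and 203 lower, in high-complexity cells 89 and 233, and 161 and 201 without mitochondrial and ribosomal protein genes in the total.

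Over the inhibitor's course, some genes were ordered from each day to the next, among them the collagen IV chains COL4A1 and COL4A2, which stood lower on each later day. Of 5326 genes 1033 (19.4%) were ordered across the 4 days, where 1 in 12 would be under random order. In high-complexity cells 911 of 5553 (16.4%) were ordered. Genes of the same 4 libraries are not independent, and the share of low-complexity cells rose in the same order. The excess over random order was therefore not taken as a result. With a 2-fold difference between the ends 42 went up and 213 down, against 108 and 68 under TMM factors and 77 and 62 in high-complexity cells. Those that went up included PTX3 (log2 3.40 between the ends), SOD2 (2.60), TXNIP (2.14), CFD (2.16) and SERPING1 (1.94), and those that went down included ADAM12 (-3.45), COL4A1 (-2.81), COL4A2 (-2.38) and COL1A1 (-1.97). These examples were chosen after their values were seen, and all were also ordered in high-complexity cells.

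Reported targets of miR-200b, which would be released from repression if the inhibitor lowered its activity, were not higher with the inhibitor. ZEB1 stood at 115 CPM with the inhibitor and 139 CPM with the control hairpin on day 1 (log2 -0.28), and at 84.9 and 103 CPM on day 7 (log2 -0.28), with 105 CPM in untreated cells. ZEB2 stood at 45.6 and 114 CPM on day 1 (log2 -1.32, fold interval 2.43 to 2.57), and at 38.4 and 91.2 CPM on day 7 (log2 -1.25, fold interval 2.30 to 2.45), with 62.9 CPM in untreated cells. Of 30 reported targets 2 were at least 1.5-fold higher and 14 lower on day 1 (median log2 -0.56, WASF3 -1.50, JAG1 -1.40) and 1 higher and 16 lower on day 7 (median log2 -0.61). Under TMM factors these medians were -0.12 and -0.21. Against untreated cells the medians were -0.18, 0.00, -0.17 and -0.40 on days 1, 3, 5 and 7, and -0.17, -0.04, -0.02 and -0.11 under TMM factors. Among 12032 genes, the 2497 with the seed match CAGTATT in a 3' UTR had a median log2 ratio to CI that differed from that of the other genes by -0.215 on day 1 and -0.263 on day 7. Against random lists matched for expression the gap was small: the median with the site was -0.517 against -0.483 on day 1 (percentile 0.9 of 10000 lists) and -0.518 against -0.478 on day 7 (percentile 0.1). For the ratio to untreated cells the difference was -0.024, -0.074, -0.142 and -0.086 on days 1, 3, 5 and 7, and in high-complexity cells -0.022, -0.068, -0.100 and -0.029. Against 420 permutations of the seed's bases, the site's difference ranked 335 and 411 from the highest in the comparisons with CI on days 1 and 7, so genes with the site were not set apart upward.

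Cells with several vascular markers together, as endothelial cells have, were few at equal depth. Cells with UMIs of at least 2 endothelial markers at 5000 UMIs were 0.493% (0.349 to 0.676) of untreated cells, 0.648%, 0.440%, 0.367% and 0.174% (0.0993 to 0.282) of MI cells on days 1, 3, 5 and 7, and 0.588% and 0.131% of CI cells on days 1 and 7. Keratinocyte markers gave 1.04%, 0.501%, 1.44%, 0.851%, 0.716%, 0.294% and 2.13% in the same order. Some of them were expressed in these fibroblasts, as KRT10 was at 169 CPM in untreated cells, so their shares gave no clean background. Melanocyte markers gave 0 cells in every library and immune markers 1 to 5 cells. Without the reduction to 5000 UMIs the endothelial shares were 8.23%, 15.4%, 11.2%, 6.58%, 2.63%, 18.4% and 10.0%, and the keratinocyte shares 5.77%, 4.29%, 11.5%, 5.69%, 4.80%, 4.41% and 14.5%.

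Clustering of all cells gave 10 clusters, of which 5 drew more than 80% of their cells from 1 library. The dividing cluster, defined by CDC20, UBE2C and CDK1, drew 48.7% of its 2935 cells from the day 3 inhibitor library, and held 1 cell of each CI library. Other defining genes were APCDD1, FABP3 and HMGCS1 in the cluster that was 96.7% untreated cells, MMP1 and SOX4 in that of MI day 1, PRG4 in that of CI day 1, and CCL2 and FOSB in a small CI day 7 cluster of 619 cells. The top genes of the CI clusters also included TOMM6, TUBB3, EEF1G and PALM2-AKAP2, whose counts were uncertain, and these clusters held 0 untreated or MI cells, so the clusters split along the processing as much as along the hairpin. A cluster of 10129 cells was defined by TXNIP, ADM, JUNB, SERPING1 and ZFP36, and clusters of 7609 and 4733 cells, marked by TAGLN, were 76.6% and 70.3% low-complexity cells. No cluster was defined by endothelial genes.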

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

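All of the tests of explanations below were chosen only after the result was seen. The results that follow were raised because the MI and CI libraries went opposite ways between day 1 and day 7, and with 1 library per group the difference was not tested. The TGF-beta response list had a difference of -0.92, from a median log2 of -0.52 with the inhibitor and 0.47 with the control hairpin. The prostaglandin receptor PTGFR had a difference of 2.17, from log2 1.14 with the inhibitor and -1.03 with the control hairpin. The protease inhibitor TFPI2 had a difference of -2.78, from log2 -1.31 with the inhibitor and 1.47 with the control hairpin.

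The same genes differed between the MI and CI libraries on both days. Gene models that overlap a gene listed in only some libraries were argued against as the whole source, since 22.6% of the shared genes had such a model, but gene models that differ without such overlap were not examined and stayed open with the processing. Separate processing of the MI and CI libraries cannot be told apart from an effect of either hairpin, because the correlation of 0.85 across genes between the days would follow from each and the hairpin was confounded with the software version. For the same reason an inhibitor that moves genes away from the untreated level stayed open, as only 3.31% of the genes lay farther from untreated cells in MI than in CI on day 1 but the untreated library shared its processing with MI. A difference of donor or culture between the hairpins also stayed open.

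Low-complexity cells were common on day 7. The inhibitor as their source was argued against, since they made up 61.9% of cells in the CI library of day 7, no fewer than in MI. Fewer UMIs per cell were argued against, since the share of nuclear RNA in the low-complexity cells of MI on day 7 was 0.00651 times that of the other cells, and fewer UMIs would not remove one class of RNA. The short-lived immediate early transcripts had a median log2 of -3.8 in these cells against the others. This could not decide for a loss of nuclear RNA, since the class was chosen for few genes and other lists were lower too. Among them were glucocorticoid response (-2.92) and p53 genes (-2.65), while common reference (0.01) and ribosomal protein genes (0.56) were not lower. Whether these barcodes were cells without nuclei or fragments of cells, and whether they arose in the culture or in the handling, stayed open.

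Cholesterol synthesis genes were lower on day 7 than in untreated cells. The inhibitor as the whole source was argued against by a median log2 of -1.49 with the control hairpin on day 7, and low-complexity cells by a median of -1.41 with the inhibitor in high-complexity cells alone. A change of medium cannot be told apart from the delivery itself, since no library had the medium without the delivery. The median was already -0.90 on day 1 of the inhibitor. Cells were put in the medium only after a day, so how much of it the day 1 libraries had was not known. On day 1 of the control hairpin the median was -0.31, so a part for the inhibitor on that day stayed open, with the scaling and processing.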

How the results depend on the processing

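The settings named high-complexity cells, cells with nuclear RNA and without overlapping genes were chosen after seeing the data, and the others before the data were examined. With 1 library per group only counting depth limits the intervals, and no setting measures the spread between cultures. Of the summary results 146 moved and 157 stayed the same, with 0 reversed. Shares, the number of clusters and the counts without overlapping genes could only be called moved or the same, so the 0 says little about direction. The balance of higher and lower genes in MI against CI on day 1 turned around under TMM factors. Of the list medians 648 moved by at least 0.1, 801 stayed and 1 reversed, and of the log2 ratios of named genes 758 moved by at least 0.1, 745 stayed and 0 reversed. Not all of the list medians counted below were labelled, as under TMM factors 118 moved and 27 stayed. A small named ratio could change sign without being counted as reversed. ETS1 between the days of MI stood at log2 -0.17, and at 0.14 in high-complexity cells. A median was called reversed only if it stood past 1.5-fold and at either end of the random lists in the main setting. Of 319 list medians over all comparisons, 52 took the opposite sign under TMM factors, none of them larger than 0.44 in size in the main setting. All barcodes, the longer seed match, the shortest 3' UTR and the setting without overlapping genes moved 0 summary results. The setting without doublets was not run, because the caller found almost none. The cause was not tested for any value below, except that a lower fold or a higher expression floor changes the counts by its construction. The choice of non-cycling cells likewise removes division transcripts by its construction.

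Pairs below give higher and lower genes in the order MI against CI on days 1 and 7, MI against untreated cells on days 1, 3, 5 and 7, CI against untreated cells on days 1 and 7, day 7 against day 1 in MI, the same in CI, and the difference between these. At 1.5-fold the pairs were 799 and 1687, 442 and 1387, 120 and 184, 539 and 302, 179 and 484, 137 and 929, 1536 and 712, 775 and 975, 243 and 1152, 360 and 1071, and 422 and 753. With a floor of 100 CPM they were 167 and 114, 54 and 115, 9 and 16, 28 and 36, 17 and 41, 10 and 57, 122 and 156, 114 and 133, 21 and 76, 57 and 53, and 16 and 86, and the genes ordered over the days of MI were 15 and 47.

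With no floor and 1 CPM added, 1632 genes were lower in MI than in CI on day 1, and 1608 genes were higher in CI than in untreated cells on day 1. The pairs for the others in the order above were 233 and 1140, 62 and 105, 289 and 221, 98 and 239, 97 and 363, 927 and 618, 183 and 546, 256 and 543, and 261 and 331.

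Under TMM factors the pairs were 849 and 181 for MI against CI on day 1 and 460 and 194 on day 7. They were 94 and 87 for MI on day 7 against untreated cells, 182 and 755 for CI on day 1 against untreated cells, 172 and 124 between the days of MI and 264 and 77 between those of CI. On day 5 of MI 65 genes were higher than in untreated cells, and the genes ordered over the days were 108 and 68.

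In high-complexity cells 82 genes were lower on day 5 of MI than in untreated cells, and the pairs were 70 and 84 for MI on day 7 against untreated cells, 688 and 246 for CI on day 7, 130 and 116 between the days of MI and 190 and 88 between those of CI. The genes ordered over the days were 77 and 62. In cells with nuclear RNA the pairs were 63 and 77 for MI on day 5, 70 and 95 for MI on day 7, 123 and 126 between the days of MI and 196 and 81 between those of CI, and 713 genes were higher in CI on day 7 than in untreated cells.

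With equal weight per cell, lower genes against untreated cells were 442 and 890 for MI on days 5 and 7 and 1062 for CI on day 7, and between the days 1013 in MI and 1885 in CI. The difference between the courses had 203 higher genes, and the immediate early list in CI on day 7 against untreated cells reversed from a median log2 of 0.70 to -0.22. In non-cycling cells 34 genes were higher on day 3 of MI than in untreated cells, 372 and 466 were lower on days 5 and 7, and 692 and 628 were lower between the days of MI and CI. With the stricter cell filter 99 genes were lower on day 7 of MI than in untreated cells, and 137 and 168 were lower between the days of MI and CI. Without mitochondrial and ribosomal protein genes in the total, 167 genes were lower on day 3 of MI than in untreated cells and 161 were higher in the difference between the courses. At Leiden resolution 1.0 there were 19 clusters.

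Shares of cells follow in the order untreated, MI on days 1, 3, 5 and 7, and CI on days 1 and 7. Without thinning, cells with at least 2 endothelial markers were 8.23%, 15.4%, 11.2%, 6.58%, 2.63%, 18.4% and 10.0%, and cells with at least 3 UMIs of G2 and M phase genes were 95.2%, 90.5%, 91.8%, 67.3%, 56.1%, 94.0% and 48.9%. Thinned to 1000 UMIs, the endothelial shares were 0.0126%, 0.0384%, 0.0184%, 0.0%, 0.0191%, 0.0548% and 0.0%. With at least 5 UMIs of G2 and M phase genes the cycling shares were 33.9%, 28.2%, 61.1%, 26.6%, 15.2%, 26.6% and 10.5%, against 61.2%, 57.9%, 77.7%, 46.7%, 35.5%, 51.8% and 22.2% in the main setting. By these shares CI on day 1 stood below untreated cells, while by MKI67 or TOP2A it stood above them (14.8% against 11.8%). The measures thus ranked the libraries differently.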

Other observations

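The comparisons and lists in this part were fixed before the data were examined, except those of low-complexity cells and of ribosomal genes, which were chosen only after the data were seen. The metallothionein genes MT2A and MT1E stood at log2 2.66 and 2.36 with the inhibitor against the control hairpin on day 1, while ZBTB16 of the same glucocorticoid list stood at -2.70. That list as a whole had 5 of 15 genes higher and 5 lower (median log2 -0.28, and 0.16 with the opposite sign under TMM factors). Adipocyte genes had 3 of 4 lower with the inhibitor (median log2 -3.67, and -3.22 under TMM factors, CD36 -5.75, FABP4 -4.61), and pericyte and smooth muscle genes 6 of 9 lower (median log2 -1.72, and -1.13 under TMM factors, STEAP4 -2.55, CSPG4 -1.44). Keratinocyte genes had 1 of 6 higher and 1 lower (median log2 0.08, and 0.53 under TMM factors), and Schwann cell genes 2 of 4 lower (median log2 -0.42, and 0.03 with the opposite sign under TMM factors).

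Genes of the microRNA machinery, which make and load microRNAs, had 8 of 14 lower and 1 higher with the inhibitor than with the control hairpin on day 1 (median log2 -0.70, and -0.25 under TMM factors, AGO4 -1.87, DGCR8 -1.34). Random lists matched to genes with a seed match had a median of -0.483 in this comparison. That value was not matched to this list or to the chromatin modifiers, so it was only a rough mark for their medians. Chromatin modifiers had 12 of 19 lower and 1 higher (median log2 -0.70, and -0.26 under TMM factors, TET1 -2.61, KDM6A -1.61), and the transcripts of the mitochondrial genome 10 of 13 lower and 1 higher (median log2 -1.02, and -0.58 under TMM factors, MT-ATP6 -1.96). In CI against untreated cells the mitochondrial transcripts had 10 of 13 higher and 0 lower on day 1 (median log2 0.97, and 0.53 under TMM factors). Common reference genes had 3 of 15 higher and 1 lower (median log2 0.39, and 0.83 under TMM factors) between the hairpins on day 1. The unfolded protein and integrated stress response genes had 8 of 20 higher and 3 lower on day 7 of the inhibitor against untreated cells (median log2 0.06, and 0.35 under TMM factors, DDIT4 1.39, PSAT1 1.39). ASNS of that list, which was higher with the inhibitor than with the control hairpin (log2 4.11), has an overlapping gene model and was uncertain, as was IRF9 of the interferon list (log2 -3.54).

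Low-complexity cells of day 7 had higher ribosomal protein genes than the other cells of the same library (median log2 0.56 in MI and 0.84 in CI), and lower immediate early genes (median log2 -5.50 in CI). Their median share of nuclear RNA was 0.0149% in MI against 2.28% in the other cells, and their median depth was 8700 against 26691 UMIs.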
